A study of Arabidopsis thaliana with 6 samples.

How the data were processed

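RNA was measured by paired-end sequencing in 6 libraries of Arabidopsis thaliana seedlings, all carrying 35S::CUC2-GR, per the labels. This transgene expresses the transcription factor CUC2 from a strong viral promoter as a fusion to the hormone-binding domain of the glucocorticoid receptor (GR), which dexamethasone (Dex) binds. Per the labels, seedlings at Boyes stage 1.02 were grown in vitro at 21 °C in long days, polyA RNA was selected from 10 µg of RNA, and the TruSeq libraries were not stranded. The 3 Dex libraries came from seedlings given 10 µL of dexamethasone in 10 mL of liquid medium for 6 h, and the 3 no_Dex libraries are described as untreated. The concentration of the dexamethasone, the time of harvest and any mock treatment are not given in the sources used here.

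The authors aligned the reads with Bowtie2 to TAIR10 per the submitters' processing notes, which state no version. Per the file headers, the deposited values are raw counts of read pairs per gene model, properly paired on opposite strands, with no insert size limit. A second column of deposited values holds counts of single reads, and a further column, of the unit other, holds the length of the gene model in bases per the file headers. Per the file headers, reads whose best and second-best hits scored alike were removed, so counts of near-identical genes are incomplete. With no strand information, transcripts that overlap on opposite strands were counted together. The count for CUC2 sums the transgene and the endogenous gene.

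Each file held 33602 gene models, of which 32835 matched a locus tag of the reference annotation and 10654 had a symbol there. Positions are those of TAIR10.1, because the files carry no coordinates, and 12298 models (36.6%) had the length of a TAIR10.1 transcript. Between 26161582 and 29481253 pairs were counted per library, which was 95.2% to 95.6% of the pairs read. A median of 513 pairs was counted per tested gene and library. Intervals on shares of pairs are exact Clopper-Pearson intervals at 95%, and a count of 0 was taken to allow up to 3 pairs, which is 0.102 to 0.115 counts per 1e6 pairs (CPM). These intervals and limits cover counting error only.

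Everything from CPM onward was computed here. edgeR 4.0.16 in R 4.3.3 removed gene models with low counts (filterByExpr, minimum count 10, minimum total 15), scaled libraries by the trimmed mean of M values (TMM), and tested Dex against no_Dex with the two-sided quasi-likelihood test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left out 12258 gene models, of which 6551 had no pair in any library, and 21344 genes were tested. CPM are given as mean ± SD of 3 libraries, and log2 fold changes (Dex minus no_Dex) with a standard error (SE). This SE was derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic.

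The 36 gene lists with 520 members were tested with camera from limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Lists with under 3 tested members were described by their values. The same test with a correlation estimated from the data, and fry, were run beside it. Each list also has the number of its members called when adjusted over all genes and when adjusted over the list alone.

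The test, the filter, the gene lists and the rule for named genes were fixed before the data were examined. The rule named CUC1, CUC2 and CUC3; the 12 genes with a symbol that rose most and the 12 that fell most among called genes with no overlap of the groups and a mean log2 CPM of at least 1; every called member of the boundary, CUC2 and KNOX lists; up to 4 members with the smallest p of each other list that was called or had a called member; and the reference genes ACT2, UBQ10 and PP2AA3. It gave 159 genes, of which 123 were called. Genes outside it are marked in the text.

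The replicate numbers are shared by both groups, and the labels do not say what they mark. Deviations from the group means correlated across genes at 0.171, 0.119 and 0.125 between libraries with the same number, and at most at 0.0177 between others. On the evidence of the data alone, the numbers were treated as pairing the libraries in alternative fits only, with the replicate number as a block. The main tests of genes and lists were unpaired. No libraries were duplicates of each other.

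The test was tested on simulated data with 21231 genes tested and 50 genes changed per fold. A further list of genes was lowered in the same data to check the list test. The test called 12% of 1.25-fold, 70% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes. These were 6, 35, 44 and 50 genes, beside 17 false calls. Alternatives fixed beforehand were DESeq2 1.42.0 size factors, no filter, at least 1 CPM in all 6 libraries, the DESeq2 Wald test, limma-voom, the replicate block, a minimum fold change of 1.5, the other list tests, and leaving out each library in turn. Alternatives chosen after seeing the data were counts of single reads, and offsets that removed trends with gene length and GC content (splines with 5 degrees of freedom), without and with the block. Figures were drawn with Python 3.11.15. No library was left out of the comparison.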

Results

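The data are read-pair counts from 6 libraries of whole Arabidopsis seedlings that carry 35S::CUC2-GR, 3 treated with dexamethasone for 6 h (Dex) and 3 untreated (no_Dex). The series' design text calls them biological replicates. CUC2 is a NAC transcription factor that sets the boundaries between organs and shapes leaf margins, and dexamethasone lets the fusion protein enter the nucleus. The pairs counted were 29481253, 28522853 and 28378873 in no_Dex replicates 1 to 3 and 29046312, 26161582 and 28231338 in Dex replicates 1 to 3. The 10 most abundant genes took 3.32% to 3.97% of the pairs. Correlations of log2 CPM across genes, which are not independent replicates, were 0.994 or 0.995 among the no_Dex libraries and 0.994 between Dex replicates 2 and 3. Dex replicate 1 stood apart, at 0.988 and 0.987 with the other Dex libraries. The first principal component (53.8% of the variance) separated the groups, and the second (21.6%) separated Dex replicate 1 from the other Dex libraries.

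The comparison of Dex with no_Dex asks which transcripts change when CUC2-GR seedlings are treated. Of 13 genes of the CUC2 and leaf-margin list 5 rose (3 without no_Dex replicate 2 or Dex replicate 2), and EPFL2 among them rose by 2.09 on the log2 scale (SE 0.22, n = 3 per group). Of 26 auxin response genes 9 fell and 2 rose, and of 26 xyloglucan endotransglucosylase/hydrolases 11 fell and 2 rose. Of 14 expansins 6 fell, and of 19 genes of photosynthetic cells 7 fell. Without no_Dex replicate 1 or 2 the hydrolase count was 6 and the photosynthetic count 0. The count of CUC2, which sums the transgene and the endogenous gene, did not pass the test. Most changes were small: of the 3071 genes called, the median absolute log2 fold change was 0.50, and 217 genes rose and 225 fell at least 2-fold. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1279 genes rose and 1792 fell, which is 14.4% of the 21344 tested. In all 3071 the 3 Dex values lay on one side of the 3 no_Dex values. Among all tested genes 7757 (36.3%) had no overlap, where chance gives 10%.

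**Figure D1:**
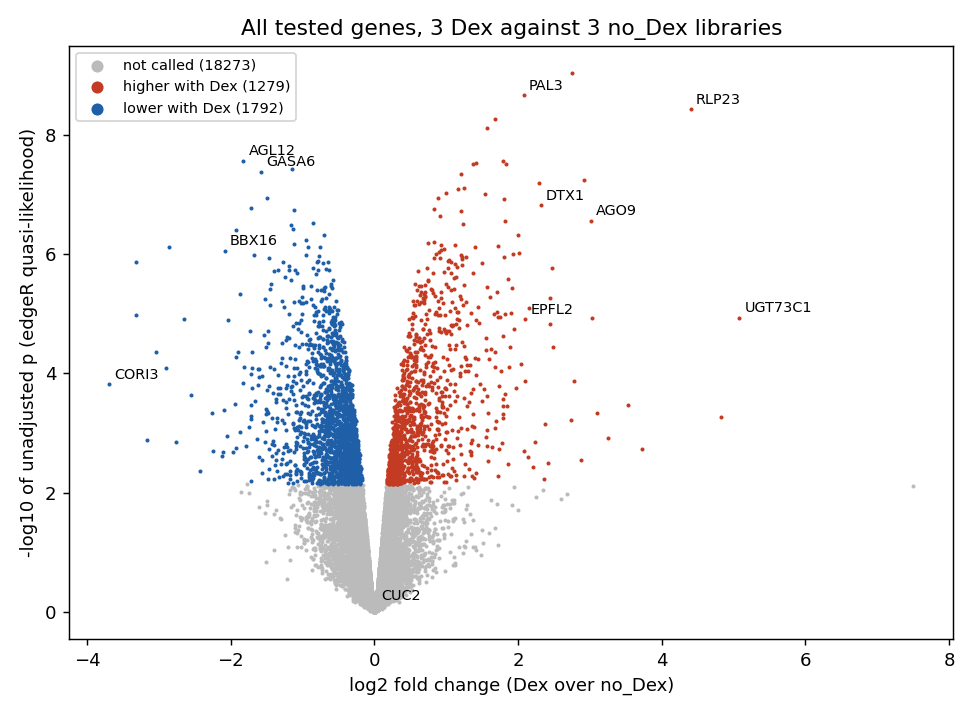
Log2 fold change (Dex minus no_Dex, horizontal axis) against the negative log10 of the unadjusted p (vertical axis) for the 21344 genes tested by edgeR. Coloured points are the 1279 genes called higher and the 1792 called lower by the adjusted p, and grey points were not called.

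These p-values measure the spread between the samples, and an exact permutation test of a single gene could not go below 0.1 with 3 libraries against 3. The labels list no mock treatment and no line without the transgene, so responses to dexamethasone or handling and responses to CUC2-GR were not separable. The counts depended on single libraries. Without Dex replicate 1, 2339 genes were higher and 2726 lower. Without no_Dex replicates 1, 2 and 3 the higher counts were 688, 519 and 617 and the lower counts 1007, 785 and 918. Without Dex replicate 2 they were 718 and 1041, and without Dex replicate 3 they were 872 and 1364. With a minimum fold change of 1.5, 124 genes were higher and 77 lower. With length and GC offsets 1645 were higher and 1616 lower, so the excess of genes lower depended on the processing.

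CUC2 (AT5G53950, chromosome 5, 21901704 to 21903854, minus strand) stood at 853 ± 32.4 CPM (SD, n = 3) in no_Dex and 864 ± 9.23 CPM (SD, n = 3) in Dex. Its log2 fold change was 0.02 (SE 0.06), with an edgeR adjusted p of 0.876. CUC2 took 0.0829% to 0.0882% of the pairs in each library; the exact 95% interval was 0.0871% to 0.0893% in no_Dex replicate 1. Its related boundary genes were far less abundant. CUC1 (AT3G15170) was at 2.97 ± 0.474 CPM in no_Dex and 2.67 ± 0.181 CPM in Dex, and CUC3 (AT1G76420) was at 0.594 ± 0.101 and 0.527 ± 0.138 CPM. Neither was called by edgeR (adjusted p = 0.550 and 0.729).

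The CUC2 and leaf-margin list, which also holds other NAC genes such as NAC1 and ORE1, had 13 tested members. Of these 5 rose, none fell and 8 were not called. Adjusted over the list alone, 5 were higher and 1 lower. EPFL2 (AT4G37810, chromosome 4, 17780729 to 17781813, plus strand), a secreted peptide that promotes leaf teeth, rose from 1.12 ± 0.261 to 4.79 ± 0.996 CPM, a log2 fold change of 2.09 (SE 0.22; edgeR adjusted p = 0.00112). CYP78A5, a cytochrome P450 that promotes organ growth, rose by 0.70 (SE 0.09; edgeR adjusted p = 0.00194). NGAL1, a repressor of CUC genes, rose by 0.66 (SE 0.10; edgeR adjusted p = 0.00483). Its relative NGAL2 rose by 0.82, a call lost without no_Dex replicate 1, no_Dex replicate 2 or Dex replicate 2 (edgeR adjusted p = 0.0787, 0.0881 and 0.0683). NAC1, an auxin-responsive NAC gene, rose by 0.28, a call lost without no_Dex replicate 2 or 3 or Dex replicate 2 or 3 (edgeR adjusted p = 0.162, 0.146, 0.0583 and 0.0980) and with length and GC offsets (0.0662). The list ranked higher than other genes by camera (adjusted p = 0.0452; adjusted p = 0.361 with an estimated correlation), and its median log2 fold change was 0.28. That call was lost without no_Dex replicate 3 (camera adjusted p = 0.0596) and without Dex replicate 1 (0.0905). The number of members called higher lay between 3, without no_Dex replicate 2 or Dex replicate 2, and 5, without Dex replicate 1. With the replicate block 7 rose and 1 fell.

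**Figure D2:**
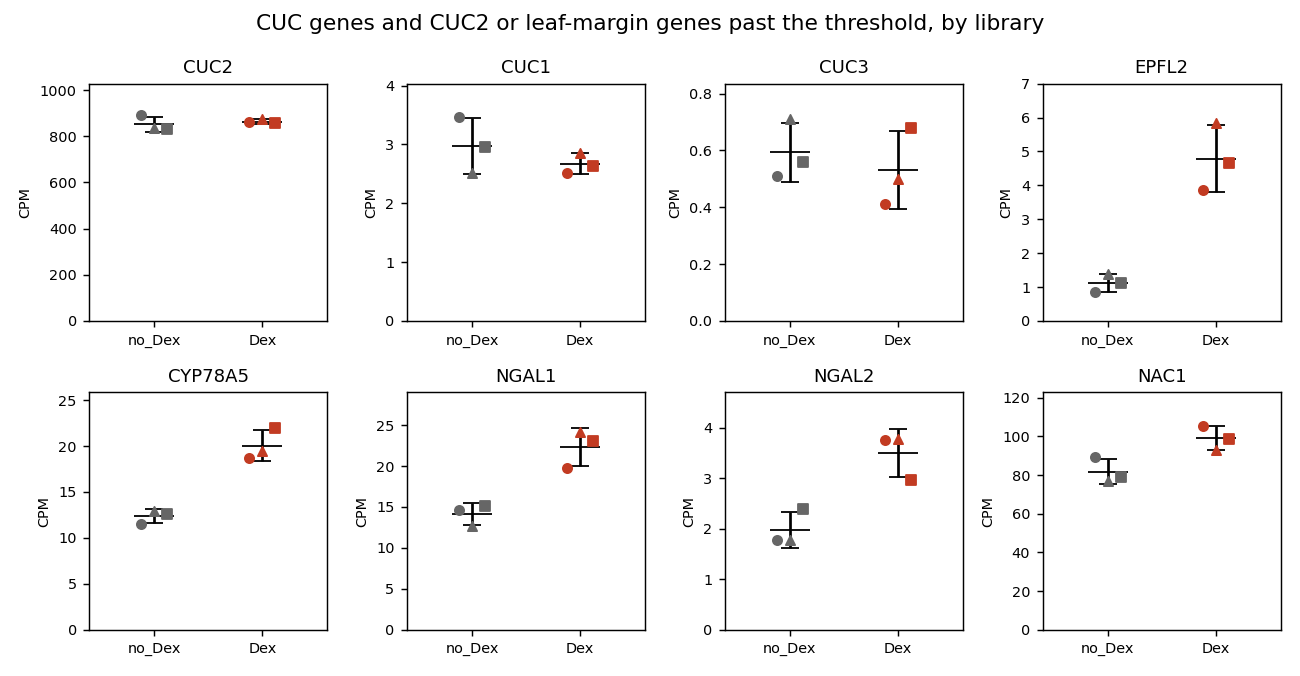
Expression in CPM (vertical axis) of the 3 CUC genes and the called genes of the CUC2 and leaf-margin list in no_Dex and Dex, with a point per library (circle, triangle and square for replicates 1, 2 and 3) and bars for the mean ± SD (n = 3). EPFL2 rose from 1.12 to 4.79 CPM, while CUC2 was at 853 and 864 CPM.

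Other regulators of organ boundaries and of the shoot meristem were not called as lists by camera. Of 18 tested boundary genes, 1 rose, 2 fell and 15 were not called, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.705). RAX3, a MYB gene of axillary meristems, fell by 0.75 on the log2 scale (SE 0.11; edgeR adjusted p = 0.00485). Its relative RAX2 fell by 0.37 and the boundary gene LSH3 rose by 0.56. The RAX2 call was lost without no_Dex replicate 1, 2 or 3 (edgeR adjusted p = 0.0532, 0.0698 and 0.0603), as was the LSH3 call (0.0542, 0.0627 and 0.0612). Boundary genes higher without Dex replicate 1 numbered 3, and 2 with the replicate block. Of 11 KNOX and meristem genes, 1 rose, 2 fell and 8 were not called, with the same counts of 1 and 2 adjusted over the list alone (camera adjusted p = 0.636). CLV1, the receptor kinase that restricts the stem cell domain, fell from 88.1 ± 7.70 to 55.8 ± 7.41 CPM (log2 fold change -0.66, SE 0.10; edgeR adjusted p = 0.00528). BLR, a homeodomain partner of KNOX proteins, rose by 0.32, a call lost without no_Dex replicates 1, 2 or 3 or Dex replicates 2 or 3 (edgeR adjusted p = 0.0693, 0.0585, 0.0838, 0.0629 and 0.0710). AS1, a MYB repressor of KNOX genes, fell by 0.50, a call lost without no_Dex replicate 2 or 3 or Dex replicate 2 (0.0938, 0.0810 and 0.0663).

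The TCP and GRF regulators of leaf growth had 18 tested members, with 1 higher and 1 lower, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.664). GRF3 rose by 0.29 on the log2 scale, a call lost without no_Dex replicate 2 (edgeR adjusted p = 0.0570), and GRF9 fell by 0.70, a call lost without no_Dex replicates 2 or 3 or Dex replicate 2 (0.105, 0.0811 and 0.0686). Without Dex replicate 3, 3 members were lower. Without Dex replicate 1, 2 were higher, with GRF8 added (edgeR adjusted p = 0.0324). GRF5 had a log2 fold change of -0.95 (SE 0.27; edgeR adjusted p = 0.0526) and was not called. GRF5 was called lower with the block (0.0206, or 0.0247 with length and GC offsets), without Dex replicate 1 or 3 (0.0387 and 0.00429), with no low-count filter, by DESeq2 and by limma-voom. Of 14 leaf polarity genes, 1 fell and 13 were not called, with 1 lower adjusted over the list alone (camera adjusted p = 0.175). REV, a homeodomain gene of the upper leaf side, fell by 0.21. That call was lost without no_Dex replicates 1, 2 or 3 or Dex replicates 2 or 3 (edgeR adjusted p = 0.0686, 0.105, 0.0680, 0.0741 and 0.0722) and with length and GC offsets (0.126, or 0.104 with the block). In the polarity list 3 were lower and 1 higher without Dex replicate 1.

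The 24 genes with the largest changes that the rule named were called under every alternative run for single genes in which they were tested. UGT73C1, RLP23, AGO9, ERF12, MYB39, CORI3, BBX16 and GAT1_2.1 were left out by the filter of at least 1 CPM in all 6 libraries. UGT73C1, a glycosyltransferase, rose most among these, from 0.163 ± 0.0413 to 5.67 ± 2.63 CPM (log2 fold change 5.08, SE 0.54, edgeR adjusted p = 0.00108). Its no_Dex libraries held 4, 4 and 6 pairs, near the floor of 3 pairs, so the size of this rise is uncertain. RLP23 (AT2G32680), an immune receptor-like protein, rose from 0.595 ± 0.167 to 12.6 ± 0.819 CPM (4.40, SE 0.17; edgeR adjusted p = 2.67e-05), and its neighbour RLP22 rose by 1.99. AGO9, an argonaute protein of small RNA pathways, rose by 3.01, the transcription factors ERF12 and MYB39 by 2.49 and 2.47, and the efflux transporter DTX1 by 2.31. The chitinase ChiC rose by 2.28, the phenylalanine ammonia-lyase PAL3 by 2.08, the senescence NAC gene NAP by 2.04, the acyltransferase GPAT7 by 1.95 and EDA36 by 1.93. PAL3 went from 19.3 ± 1.69 to 81.4 ± 3.58 CPM (SE 0.07; edgeR adjusted p = 2.34e-05). Of those that fell, CORI3, a coronatine-induced gene, fell most, from 8.29 ± 4.26 to 0.652 ± 0.510 CPM (log2 fold change -3.69, SE 0.56; edgeR adjusted p = 0.00478). The B-box gene BBX16 fell by 2.09 on the log2 scale, RL4 by 1.93, CYP78A8 by 1.90, the root MADS-box gene AGL12 by 1.83 and the immune monooxygenase FMO1 by 1.71. GAT1_2.1 fell by 1.70, the trehalose-phosphate phosphatase TPPJ by 1.68, the gibberellin-regulated peptide GASA6 by 1.58 and the protochlorophyllide reductase PORA by 1.51. Of the neighbouring ferric reductase genes, FRO6 fell by 1.83 and FRO7 was 3.04-fold lower. RLP22 and RLP23, like FRO6 and FRO7, are related neighbours, and reads that matched both equally well were not counted.

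Both auxin lists ranked lower by camera. Of 26 tested auxin response genes, 2 rose, 9 fell and 15 were not called, with 3 higher and 15 lower adjusted over the list alone. The list ranked lower by camera (adjusted p = 0.00112; adjusted p = 0.361 with an estimated correlation), with a median of -0.37. IAA3, IAA19 and IAA17, repressors that auxin itself induces, fell by 0.80, 0.86 and 0.58, and the auxin-conjugating enzyme GH3.5 fell by 0.62. IAA19 went from 39.1 ± 1.82 to 21.6 ± 1.57 CPM (SE 0.07; edgeR adjusted p = 0.000440). The 2 that rose were GH3.1 and GH3.2, chosen after their values were seen. GH3.1 rose by 1.32 and GH3.2 by 0.52, and the call of GH3.2 was lost without no_Dex replicate 2 (edgeR adjusted p = 0.0591). Of 22 auxin synthesis and transport genes, 2 rose, 8 fell and 12 were not called, with 3 higher and 10 lower adjusted over the list alone. The efflux carriers PIN4 and PIN7 fell by 0.59 and 0.42, the synthesis enzyme YUC9 by 1.11 and the tryptophan aminotransferase TAA1 by 0.40. YUC1 and YUC5, the 2 that rose, were chosen after their values were seen and rose by 1.86 and 0.59. The YUC1 call was lost without no_Dex replicates 1, 2 or 3 or Dex replicates 2 or 3 (edgeR adjusted p = 0.105, 0.0876, 0.0811, 0.0878 and 0.0695). The YUC5 call was lost without no_Dex replicate 1 or 2 or Dex replicate 2 (0.0599, 0.0584 and 0.0549). This list ranked lower by camera (adjusted p = 0.0359; adjusted p = 0.437 with an estimated correlation; median -0.27). The call was lost with the replicate block (camera adjusted p = 0.0664), without no_Dex replicate 3 (0.0544) and without Dex replicate 1 (0.130), and also with no low-count filter and with single reads. The list had 4 members lower without no_Dex replicate 2 and 5 without no_Dex replicate 1. Its higher count was 4 without Dex replicate 1 and 0 without no_Dex replicate 1 or 2 or Dex replicate 2. Its members averaged -0.21 on the log2 scale in Dex replicate 1 relative to the other Dex libraries.

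Of 26 cytokinin genes, 3 rose, 6 fell and 17 were not called, with 4 higher and 10 lower adjusted over the list alone. The synthesis genes LOG7 and IPT5 fell by 0.59 and 0.72, the cytokinin oxidase CKX6 by 0.72 and the response regulator ARR5 by 0.39. CKX7, chosen after its values were seen, rose by 0.54, a call lost without no_Dex replicate 2 (edgeR adjusted p = 0.0522). ARR16 and LOG8, chosen in the same way, rose by 0.62 and 0.25. Without no_Dex replicates 1 or 2 or Dex replicates 2 or 3 the calls of ARR16 (0.0992, 0.113, 0.0903 and 0.0680) and LOG8 (0.118, 0.141, 0.114 and 0.0841) were lost. As a list the cytokinin genes ranked lower by camera (adjusted p = 0.0245; adjusted p = 0.361 with an estimated correlation; median -0.16), a call lost without no_Dex replicate 3 (0.0544). Of 14 abscisic acid and cold genes, 1 rose, 3 fell and 10 were not called, with 1 higher and 6 lower adjusted over the list alone. CYP707A2, which breaks down abscisic acid, fell by 1.23 (SE 0.21; edgeR adjusted p = 0.00816). As a group these genes ranked lower by camera (adjusted p = 0.0290; adjusted p = 0.437 with an estimated correlation; median -0.22). Without no_Dex replicates 2 or 3 or Dex replicates 1 or 2 that call was lost (camera adjusted p = 0.122, 0.0785, 0.130 and 0.0879), as it was with no low-count filter and with single reads, and the list averaged -0.36 in Dex replicate 1 relative to the other Dex libraries. Without Dex replicate 1, 5 of its members were lower, and without no_Dex replicates 2 or 3 or Dex replicate 2 the count was 1. None of them was higher without no_Dex replicate 1, 2 or 3.

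Gibberellin, brassinosteroid and ethylene genes were not called as lists. Of 13 gibberellin genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.636), and the receptor GID1B rose by 0.65. Of 15 brassinosteroid genes, 1 rose and 3 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.421). Among them PRE1 and PRE6, small proteins that promote cell elongation, fell by 1.73 and 1.21. Of 12 ethylene genes, 3 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.440). The ethylene synthesis gene ACS4 fell by 1.52 (edgeR adjusted p = 0.00838). The median of the ethylene list was 0.23 and its mean -0.06, so they differed in sign. Gibberellin genes had 0 members lower without no_Dex replicate 1 or 3 and 1 without no_Dex replicate 2 or Dex replicate 2 or 3. They had 1 higher without no_Dex replicate 1, 2 or 3 or Dex replicate 2. Brassinosteroid genes had 5 lower without Dex replicate 1, and 0 higher without no_Dex replicate 2 or 3 or Dex replicate 2 or 3. Ethylene genes had 1, 0 and 0 higher without no_Dex replicates 1, 2 and 3. They had 4 lower without Dex replicate 1, and 1 without no_Dex replicate 1 or 2. With the block 5 ethylene and 2 brassinosteroid genes were higher.

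**Figure D3:**
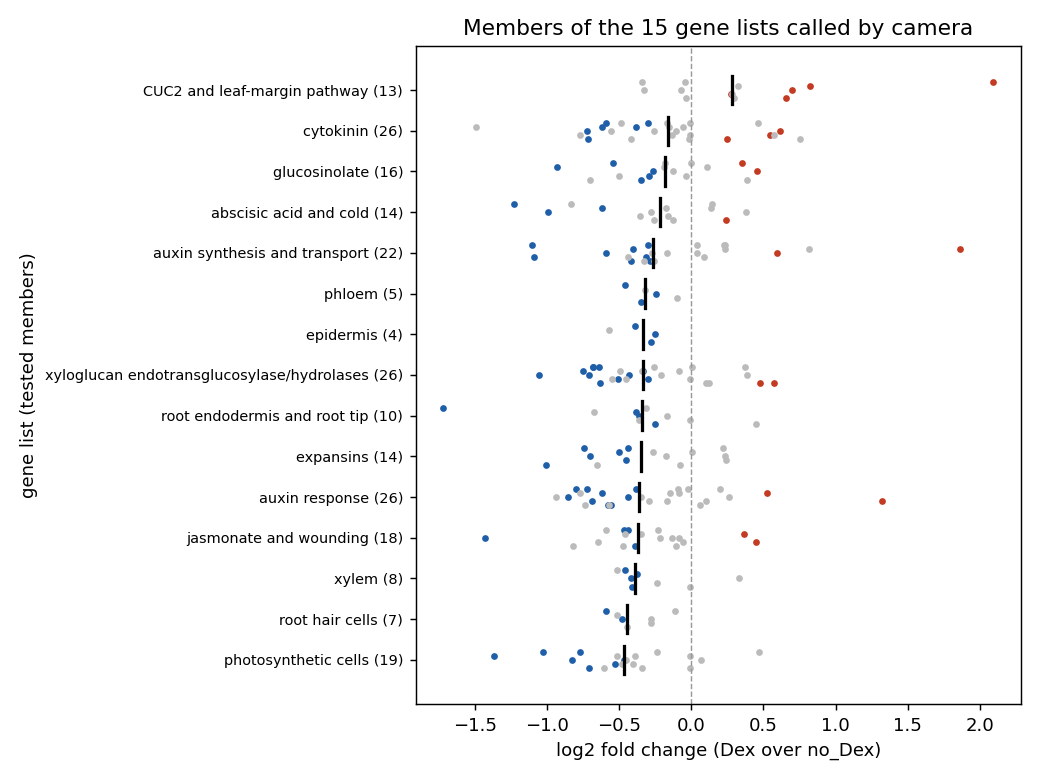
Log2 fold change (Dex minus no_Dex, horizontal axis) of the tested members of the 15 gene lists called by camera (vertical axis), with red and blue points for members called higher and lower, grey points for members not called and a black bar for the median. The CUC2 and leaf-margin list has a median of 0.28 and the auxin response list a median of -0.37.

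Both lists of genes that loosen the cell wall ranked lower by camera. Of 14 expansins, which loosen the wall as cells grow, none rose, 6 fell and 8 were not called, with 1 higher and 7 lower adjusted over the list alone. In the fit without no_Dex replicate 3 and in that without Dex replicate 1, 1 expansin was called higher. EXPA8 went from 44.5 ± 0.858 to 22.1 ± 3.52 CPM (log2 fold change -1.01, SE 0.11; edgeR adjusted p = 0.00101), and EXPA5, EXPA11 and EXPA10 fell by 0.74, 0.71 and 0.50. By camera the list ranked lower (adjusted p = 0.00790; adjusted p = 0.361 with an estimated correlation; median -0.35). Of 26 xyloglucan endotransglucosylase/hydrolases, which remodel the wall's xyloglucan, 2 rose, 11 fell and 13 were not called, with 3 higher and 14 lower adjusted over the list alone. XTH17 went from 174 ± 0.267 to 106 ± 5.65 CPM (log2 fold change -0.71, SE 0.06; edgeR adjusted p = 0.000394). XTH8 and XTH33 fell by 0.64 and 0.75, and XTH28 rose by 0.48. This list ranked lower by camera (adjusted p = 0.00187; adjusted p = 0.361 with an estimated correlation; median -0.34). Its lower count was 6 without no_Dex replicate 1 or 2, and its higher count was 1 without no_Dex replicate 1 or 2 or Dex replicate 2 or 3 and 4 with the block. Both lists stayed called without each library in turn.

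Cell cycle genes were not called as a list. Of 24, 1 fell (2 with the replicate block) and 23 were not called, and none was called in either direction adjusted over the list alone (camera adjusted p = 0.563). The call of CYCD1;1, which fell by 0.42, was lost without no_Dex replicates 1, 2 or 3 or Dex replicate 2 (edgeR adjusted p = 0.0709, 0.138, 0.105 and 0.0688) and with length and GC offsets (0.0959). Without Dex replicate 1, 4 members were higher and the list was called higher (camera adjusted p = 0.0311). With all libraries it had an adjusted p = 0.887 with an estimated correlation, and its members averaged -0.27 in Dex replicate 1 relative to the other Dex libraries. Of 9 inhibitors of cyclin-dependent kinases, 1 rose and 8 were not called, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.888). SIM, which promotes endoreduplication, rose by 0.45 (edgeR adjusted p = 0.00277). With the block 1 inhibitor fell, KRP2 (0.0459), as it did without Dex replicate 1 (0.0254). The median of this list was -0.11, opposite in sign to its mean and to its direction by camera.

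Of 18 jasmonate and wounding genes, 2 rose, 4 fell and 12 were not called, with 2 higher and 8 lower adjusted over the list alone. The jasmonate synthesis genes AOS and LOX2 fell by 0.44 and 1.43. LOX2 went from 189 ± 57.1 to 69.9 ± 21.8 CPM (SE 0.26; edgeR adjusted p = 0.0104). The list ranked lower by camera (adjusted p = 0.0147; adjusted p = 0.611 with an estimated correlation; median -0.37). The call was lost without no_Dex replicate 3 (camera adjusted p = 0.0637) and without Dex replicate 1 (0.0764). In Dex replicate 1 its members averaged -0.21 relative to the other Dex libraries. Its lower count was 2 without no_Dex replicate 2 or 3, and its higher count was 1 without no_Dex replicate 1 or 2 and 0 without Dex replicate 2 or 3. Of 16 glucosinolate genes, 2 rose, 5 fell and 9 were not called, with 2 higher and 7 lower adjusted over the list alone. MYB34, a regulator of indole glucosinolates, fell by 0.55 (SE 0.07; edgeR adjusted p = 0.00221). SOT16 and CYP83B1, which act in glucosinolate synthesis and were chosen after their values were seen, rose by 0.35 and 0.45. Their calls were lost without no_Dex replicates 1, 2 or 3 or Dex replicate 2 (edgeR adjusted p = 0.0963, 0.0746, 0.123 and 0.0547 for SOT16, and 0.123, 0.101, 0.154 and 0.0629 for CYP83B1). This list ranked lower by camera (adjusted p = 0.0421; adjusted p = 0.503 with an estimated correlation; median -0.19), a call lost without no_Dex replicate 2 or Dex replicate 1 or 2 (0.137, 0.0771 and 0.0632). Its lower count was 1 without no_Dex replicate 2, and 2 without no_Dex replicate 3 or Dex replicate 2.

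Lists that could register handling were mostly not called. Of 12 hypoxia genes, 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.148). The list was called higher with the replicate block (camera adjusted p = 0.0243), with length and GC offsets and the block (0.0488), without no_Dex replicate 3 (0.0459) and without Dex replicate 1 (0.0270). With all libraries its adjusted p = 0.779 with an estimated correlation. The sucrose synthases SUS1 and SUS4 fell by 0.79 and 0.56, and the haemoglobin gene HB1 rose by 0.66, a call lost without no_Dex replicate 2 (edgeR adjusted p = 0.0614). PCO2, an enzyme of oxygen sensing, rose by 0.69, a call lost without no_Dex replicate 1 or 2 (0.0626 and 0.0686). PCO1, HRA1 and LBD41, the others that rose, were chosen after their values were seen. They rose by 0.45, 0.67 and 0.63, and without no_Dex replicate 1 (edgeR adjusted p = 0.0835, 0.0771 and 0.124) or 2 (0.0922, 0.0942 and 0.136) none of them was called. LBD41 also lost its call without no_Dex replicate 3, Dex replicate 2 or Dex replicate 3 (0.0968, 0.0916 and 0.0922), and HRA1 without no_Dex replicate 3 (0.0509). With the block 8 hypoxia genes were higher. The hypoxia genes averaged -0.37 in Dex replicate 1 relative to the other Dex libraries. Of 14 touch and early stress genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.167). CBF2, a cold-response regulator, fell by 1.45 (edgeR adjusted p = 0.00308). This list was called lower without no_Dex replicate 3, Dex replicate 1 or Dex replicate 2 (camera adjusted p = 0.0156, 0.0491 and 0.0293) and with length and GC offsets and the block (0.0365). With all libraries the adjusted p = 0.779 with an estimated correlation. Of its members 4 were lower without Dex replicate 1 and 1 without no_Dex replicate 1 or 2, while 2 were higher without no_Dex replicate 1 and 0 without no_Dex replicate 2 or 3 or Dex replicate 2. Of 8 heat shock genes none was called by edgeR, nor adjusted over the list alone (camera adjusted p = 0.871). Of 12 iron deficiency and nitrate genes none was called, nor adjusted over the list alone (camera adjusted p = 0.705). Without Dex replicate 1, 2 of these rose and 2 fell by edgeR, and with the block 2 fell.

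Of 8 salicylate and defence genes, 1 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.664). PAD4, a regulator of salicylate signalling, fell by 0.55 (edgeR adjusted p = 0.00113). FRK1, an early immune gene, was at 12.3, 9.40 and 4.95 CPM in no_Dex replicates 1 to 3 and at 76.7, 17.8 and 11.5 CPM in Dex replicates 1 to 3. It was not called (3.99-fold, SE 0.69 on the log2 scale; edgeR adjusted p = 0.0911), though it was called higher with the block (0.0142) and without Dex replicate 3 (0.0406). The log2 fold change of FRK1 was 0.72 without Dex replicate 1. The median of this list was -0.05 and its mean 0.23, and camera placed it lower. Of 10 xenobiotic response genes, 1 rose and 1 fell, as when adjusted over the list alone (camera adjusted p = 0.705). The member that rose was DTX1; the median of the list was -0.01 and its mean 0.15. Of 10 flavonoid and anthocyanin genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.440). PAP2, an activator of anthocyanin synthesis, rose by 3.09 (SE 0.55, edgeR adjusted p = 0.00914), from 0.138 ± 0.124 to 1.22 ± 0.344 CPM. The no_Dex mean of PAP2 lies near the floor of 0.102 to 0.115 CPM, so the size of its rise is uncertain. The median of this list was -0.18 and its mean 0.10. The salicylate list had 0 higher without no_Dex replicate 1, 2 or 3 or Dex replicate 2. Xenobiotic genes had 0 lower without no_Dex replicate 1 or 2, and flavonoid genes 0 lower without no_Dex replicate 2 or 3 or Dex replicate 2 or 3. With the block 2 salicylate genes were higher, and 3 xenobiotic and 2 flavonoid genes were lower.

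Markers of 6 cell types ranked lower by camera, but none of these lists was called with an estimated correlation (camera adjusted p = 0.361 to 0.646). Of 19 genes of photosynthetic cells, none rose, 7 fell and 12 were not called, with 1 higher and 14 lower adjusted over the list alone. The light-harvesting gene LHCB4.2 fell from 647 ± 31.3 to 379 ± 85.7 CPM (log2 fold change -0.77, SE 0.15; edgeR adjusted p = 0.0141). Its call was lost without no_Dex replicate 1 or 2 (0.0531 and 0.0659). Dex replicate 1 was lower than the other Dex libraries in these genes, by a mean of -0.67. As a group these genes ranked lower by camera (adjusted p = 0.000577; adjusted p = 0.646 with an estimated correlation; median -0.47). Without Dex replicate 1, 12 members were lower by edgeR, and with the block 11. Without no_Dex replicates 1, 2 and 3 the lower counts were 0, 0 and 1, and without Dex replicate 2 the count was 4, while the list stayed called by camera in each case. The genes CAB1, CAB2 and CAB3 and the RBCS genes are near-identical, so their counts are uncertain.

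Of 7 root hair genes, none rose, 2 fell and 5 were not called, with 0 higher and 3 lower adjusted over the list alone. RSL4, which drives root hair growth, fell by 0.59 (SE 0.09; edgeR adjusted p = 0.00438). By camera the list ranked lower (adjusted p = 0.00893; adjusted p = 0.437 with an estimated correlation; median -0.45), and it averaged -0.47 in Dex replicate 1 relative to the other Dex libraries. Of 10 genes of the root endodermis and root tip, 4 fell and 6 were not called, with 7 lower adjusted over the list alone. CASP5, which builds the Casparian strip, fell by 1.72 (SE 0.25; edgeR adjusted p = 0.00358). This list ranked lower by camera (adjusted p = 0.00790; adjusted p = 0.361 with an estimated correlation; median -0.34). Of 4 epidermis genes, 3 fell and 1 was not called, with 3 lower adjusted over the list alone. The epidermal regulator ATML1 fell by 0.39 (SE 0.05; edgeR adjusted p = 0.00269). The epidermis list ranked lower by camera (adjusted p = 0.00790; adjusted p = 0.361 with an estimated correlation; median -0.33), and it averaged -0.32 in Dex replicate 1 relative to the other Dex libraries. Without no_Dex replicate 1 or 2, 1 member was called lower in each of these 3 lists. Without no_Dex replicate 3 the lower counts were 1, 2 and 1, and without Dex replicate 3 they were 2, 1 and 1. The epidermis count was 1 without Dex replicate 2. All 3 lists stayed called by camera without each library in turn.

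Of 5 phloem genes, 3 fell and 2 were not called, with 4 lower adjusted over the list alone. CALS7, a callose synthase of sieve plates, fell by 0.46, a call lost without no_Dex replicate 1 or 2 or Dex replicate 2 (edgeR adjusted p = 0.0524, 0.0659 and 0.0570) and with length and GC offsets (0.0662, or 0.0599 with the block). The list ranked lower by camera (adjusted p = 0.0147; adjusted p = 0.437 with an estimated correlation; median -0.32). Of 8 xylem genes, 4 fell and 4 were not called, with 4 lower adjusted over the list alone. CESA7, a cellulose synthase of secondary walls, fell by 0.46, a call lost without no_Dex replicate 2 or 3 (edgeR adjusted p = 0.0657 and 0.0506). As a group these genes ranked lower by camera (adjusted p = 0.0193; adjusted p = 0.534 with an estimated correlation; median -0.39). In both lists no member was called by edgeR without no_Dex replicate 2. Phloem genes also had 0 lower without no_Dex replicate 1 or Dex replicate 2 and 1 without Dex replicate 3. Xylem genes had 1 lower without no_Dex replicate 1 or 3 and 2 without Dex replicate 2. Both lists stayed called by camera without each library in turn. Of 11 stomatal lineage genes, 1 fell and 10 were not called, with 1 lower adjusted over the list alone (camera adjusted p = 0.117). It was called lower without no_Dex replicate 1, Dex replicate 2 or Dex replicate 3 (camera adjusted p = 0.0384, 0.0262 and 0.0261) and with length and GC offsets and the block (0.0483). Here too the adjusted p = 0.779 with an estimated correlation in all libraries. Stomatal genes had 2 members higher without Dex replicate 1, and 0 lower without each of the other libraries in turn. With the replicate block 3 were lower, with SPCH (edgeR adjusted p = 0.0211) and POLAR (0.0369) added. The stomatal genes averaged -0.85 in Dex replicate 1 relative to the other Dex libraries. Of 6 trichome genes, 1 fell and 5 were not called, with 1 lower adjusted over the list alone (camera adjusted p = 0.0653), and the list was called lower without Dex replicate 2 (0.0330) and with length and GC offsets and the block (0.0452). In all libraries the trichome adjusted p = 0.437 with an estimated correlation, and no member was lower without no_Dex replicate 1 or 3. Of 4 seed storage genes only CRA1 was tested, and it was not called. CRA1, a seed storage protein chosen after its values were seen, was at 0.580 CPM in Dex replicate 1 and 37.6 CPM in Dex replicate 3 (a 181-fold rise of the group, with SE 2.14 on the log2 scale; edgeR adjusted p = 0.0520). CRA1 was called higher without Dex replicate 1, 2 or 3 (edgeR adjusted p = 0.00320, 0.0475 and 0.0296) and with the replicate block (7.32e-05). It was also called by DESeq2 (0.00174), with no low-count filter (0.0366), with single reads (0.0403) and with length and GC offsets (0.0498), but not by limma-voom (0.213).

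Of 18 circadian clock genes, 2 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.629). The genes that fell are morning-phased: PRR9 fell from 5.92 ± 0.225 to 2.16 ± 0.302 CPM (log2 fold change -1.45, SE 0.13; edgeR adjusted p = 0.000655), CCA1 by 0.82 and LNK2 by 0.54. Of the evening genes FKF1 rose by 0.37, a call lost without no_Dex replicate 1 or 3 or Dex replicate 2 or 3 (edgeR adjusted p = 0.105, 0.0948, 0.0909 and 0.0772). GRP7, chosen after its values were seen, rose by 0.35, a call lost without no_Dex replicates 1, 2 or 3 or Dex replicate 2 (0.127, 0.105, 0.133 and 0.123), with at least 1 CPM in all 6 libraries and with length and GC offsets, with or without the block. Clock genes higher without Dex replicate 1 numbered 4.

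**Figure D4:**
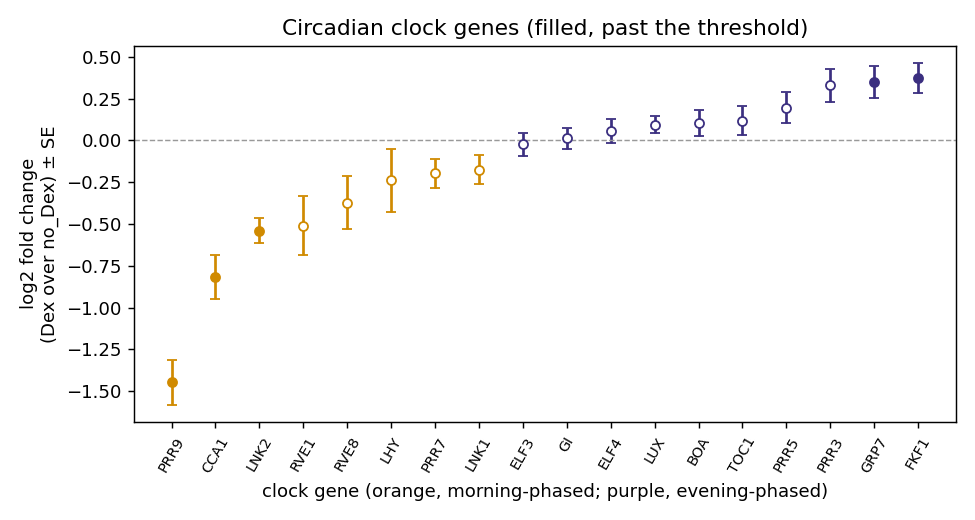
Log2 fold change (Dex minus no_Dex) ± SE (vertical axis) of the circadian clock genes (horizontal axis), orange for morning genes and purple for evening genes, filled where called by edgeR. All 8 morning genes of the list lie below 0 and 9 of the 10 evening genes above 0. Their means are -0.54 and 0.16, and only 3 morning and 2 evening genes were called.

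Of 12 reference genes, 1 rose and 11 were not called, with 5 higher adjusted over the list alone (camera adjusted p = 0.167). UBQ10 rose from 1647 ± 52.7 to 2055 ± 65.9 CPM (log2 fold change 0.32), a call lost without no_Dex replicate 2 or 3 or Dex replicate 3 (edgeR adjusted p = 0.0751, 0.0902 and 0.0713). In this list 3 genes were higher without Dex replicate 1 and 2 with the block. ACT2 had a log2 fold change of -0.18 and PP2AA3 of 0.08 (edgeR adjusted p = 0.133 and 0.330). Of the 35 lists tested, 15 were called by camera, 1 higher and 14 lower, and 9 of them stayed called without each library in turn. With an estimated correlation none of the 35 lists was called by camera, and 4 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance in one direction, 11 lists were called. Of these 9 were among the 15, and the other 2 were leaf polarity (fry adjusted p = 0.0444) and reference genes (0.0176). Those of the 15 not called by fry were abscisic acid and cold, jasmonate, photosynthetic cells, root hair, phloem and xylem. The mixed test of fry asks whether genes of a list change in either direction, and does not compare them with other genes. It called 30 lists, among them boundary (fry mixed adjusted p = 0.000316), KNOX (0.000870) and reference genes (9.58e-06). With 14.4% of all tested genes called, it cannot show a response particular to a list.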

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

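Counts of single reads and the removal of length and GC trends were chosen after seeing the data; the other alternatives were fixed before. The counts of genes higher and lower stayed within 1.5 times of 1279 and 1792 with other size factors, other filters, the DESeq2 Wald test, limma-voom, single reads and length and GC offsets. A minimum fold change of 1.5 left 124 genes higher and 77 lower, since it tests against a larger change. With length and GC offsets and the replicate block together, 1923 genes were higher and 1844 lower, and the cause was not tested. With length and GC offsets alone, 1645 were higher and 1616 lower. The excess of genes lower over genes higher in the main test was thus not kept under these settings. Leaving out a library gave 519 to 2339 genes higher and 785 to 2726 lower. The highest counts came without Dex replicate 1. Leaving out any of the other 5 libraries lowered both counts; those fits rest on fewer samples. Why the counts rose without Dex replicate 1 was not tested.

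The replicate block called 1604 genes higher and 2146 lower. It called 15 lists, losing auxin synthesis and transport and gaining hypoxia, and it gained the calls of 10 genes named by the rule; among the lists and those genes it changed no other call. It kept 1222 of the 1279 calls higher and 1717 of the 1792 lower. Leaving out a library gave 12 to 16 lists called. With an estimated correlation 0 lists were called by camera (smallest adjusted p = 0.361), 4 had an unadjusted p under 0.05, and fry called 11, of which 9 were among the 15. With length and GC offsets and the block together 19 lists were called, all 15 among them. For the genes named by the rule, 2110 of 2359 values under the alternatives kept direction and side of the threshold, 203 lost a call, 46 gained 1 and 0 reversed. Of the 123 called, 69 were called under every alternative run for single genes in which they were tested, which left out the minimum fold change. Of these 69, 15 were left out by the filter of at least 1 CPM in all 6 libraries. In simulated data with 3 libraries per group, 12% of the smallest changes added were called. That simulation changed far fewer genes than the 3071 called here, which makes the adjusted threshold stricter, and no library in it stood apart. The share therefore does not carry over to these data.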

Other observations

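Of the tests in this part, those on the clock output genes and on the splits were fixed before their result was seen, and the others were chosen after. The clock output test followed a look at the clock list. Protein families were tested by camera over 863 InterPro domains, of which 17 were called higher and 94 lower. With an estimated correlation 0 were called. Over all tested genes the log2 fold change fell with gene model length (Spearman rho -0.17). The domains were not tested with this trend removed, so families of short or long genes may rank higher or lower through it. Water channels ranked lower: of 23 aquaporin genes 1 rose (0 without each library but Dex replicate 1) and 16 fell, with a median log2 fold change of -0.62 (camera adjusted p = 8.49e-08; adjusted p = 0.759 with an estimated correlation). The plasma membrane channels RD28 and PIP2A fell by 1.11 and 0.89 on the log2 scale, PIP1B by 0.69 and the related channel NLM1 by 1.27, each called under every alternative run for single genes. Of 12 genes with the heavy chain domain of NADPH oxidases and ferric reductases, 9 fell (median -0.50; camera adjusted p = 1.05e-05; adjusted p = 0.759 with an estimated correlation), among them RBOHB by 0.69 and RHD2, which root hairs need for growth, by 0.51. Of 15 genes with a trehalose-phosphatase domain, which phosphatases and synthases carry, 6 fell (median -0.25; camera adjusted p = 0.00238; adjusted p = 0.759 with an estimated correlation), among them the phosphatases TPPH and TPPJ and the synthases TPS1 and TPS5. Of 64 SAUR genes, which respond to auxin, 4 rose and 22 fell (median -0.37; camera adjusted p = 0.00153; adjusted p = 0.759 with an estimated correlation), and SAUR28 fell by 1.48. The SAUR genes lower were 12, 8 and 6 without no_Dex replicates 1, 2 and 3 and 8 without Dex replicate 2, and 8 were higher without Dex replicate 1.

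Histone genes ranked higher: of 41 with the histone core domain 4 rose and none fell, with a median of 0.26 (camera adjusted p = 1.05e-05; adjusted p = 0.872 with an estimated correlation; 2.59e-11 without Dex replicate 1). The count of 4 depended on single libraries: it was 1, 0 and 1 without no_Dex replicates 1, 2 and 3, 0 without Dex replicate 2 or 3, 32 without Dex replicate 1, and 30 with the replicate block. Immune receptors with an NB-ARC domain ranked lower: of 157, 16 fell and none rose (median -0.13; camera adjusted p = 0.000264; adjusted p = 0.888 with an estimated correlation), and ADR1 fell by 0.54 (edgeR adjusted p = 0.00313). Among all 21344 tested genes 1792 fell, a share not far from that of the NB-ARC genes. The NB-ARC genes lower were 9 and 5 without no_Dex replicates 1 and 2 and 46 without Dex replicate 1. Their count was 7 and 10 without Dex replicates 2 and 3, and 32 with the block. The genes named here were chosen after their values were seen.

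The first pattern is that morning clock genes were lower in Dex relative to evening clock genes. In 16 clock output genes outside the list, the mean log2 fold change of 11 morning genes minus that of 5 evening genes was -1.02, with 6 of the 11 called lower and 2 of the 5 called higher. The mean log2 CPM of these morning genes minus that of the evening genes was -2.69 to -2.61 in the no_Dex libraries and -3.90 to -3.47 in the Dex libraries. The list in which the pattern was seen gave -0.70, and -0.69 without Dex replicate 1, and in both sets Dex replicates 2 and 3 lay below every no_Dex library, which argues against Dex replicate 1 alone. A later time of harvest for the Dex plants is a candidate explanation, but the labels give no harvest time, and a response of the clock to treatment was not tested.

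The second pattern is that Dex replicate 1 stood apart. Depth does not explain it, because at equal depth its higher correlation with the other Dex libraries was 0.988, against 0.994 between those 2. An untreated library under a Dex label is argued against, since of the 5065 genes called without it 5046 were also tested with all libraries, and in 66.3% of these it lay nearer to the Dex mean. A more active defence state stays open: the salicylate and defence list averaged 0.33 higher in it, at percentile 98.6 of random lists, but without FRK1 it averaged 0.03, at percentile 59.1. FRK1 was not the only gene with a large gap. Of others picked after their values were seen, AT4G12490 was at 187 CPM in Dex replicate 1 and 28.1 and 20.4 CPM in Dex replicates 2 and 3. AT5G64120 was at 414 against 99.1 and 74.9 CPM, while AT1G14960 was lower, at 13.3 against 59.6 and 76.8 CPM. These genes are not in the defence list and were not part of its test. Of the 35 lists 13 lay in the lowest 2.5% of random lists and 4 in the highest. The random lists drew each gene independently, while genes of a list can move together (estimated correlation 0.947 for photosynthetic cells). These percentiles, that of the defence list included, are therefore too extreme for such lists, and the counts do not say how many lists differ. By their means of -0.85 and -0.67, the stomatal and photosynthetic genes also differed in Dex replicate 1.

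The third pattern is that 14 lists ranked lower and 1 higher by camera, though none was called with an estimated correlation (smallest adjusted p = 0.361). With the trend of fold change with gene length and GC content removed, 14 of the 14 were still called lower, and the mean of their medians went from -0.33 to -0.30. Without Dex replicate 1, 10 of the 14 were called lower. Both values argue against these sources as the whole cause. Slower growth after CUC2-GR activation, a response to dexamethasone or immersion, and a time-of-day difference stay open and were not tested.

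The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes Dex and no_Dex libraries on each side. The difference between them then adds to the spread within each side, which makes calls unlikely, so low counts there say little about chance. As many genes higher as in the real split (1279) came from 1 split, the real one, with a highest other count of 0; the same held for genes lower (1792), 1 split and a highest other count of 0. At an unadjusted p under 0.05 the other splits had between 102 and 1482 genes by edgeR, against 6424. As many lists (15) came from 2 splits, and the highest other count was 16, in the split with no_Dex 1, Dex 1 and Dex 3 on one side. The 3 other splits that part all pairs had 0 genes called and at most 7 lists.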
